A study of Mus musculus with 5 samples.

How the data were processed

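Total RNA of mammary gland from 5 female FVB/N mice, aged 8 weeks per the labels, was measured on Affymetrix whole-transcript arrays. The comparison was between 2 control mice that carry only the MMTV-rtTA transgene and 3 mice that carry rtTA together with a cyclin D1 transgene. rtTA is the reverse tetracycline transactivator, a protein that switches on a responder transgene in the presence of doxycycline, and MMTV is the mouse mammary tumour virus promoter, which is active in mammary epithelium. The labels' treatment protocol gives 7 days of doxycycline, but words it for mice with a "KE" mutant of cyclin D1, and it does not say whether the control mice received the drug. The series' design text states that the mice were separate animals, so each array was taken as 1 biological replicate. Sample groups were taken from the sample titles.

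The deposited values are log2 expression values per probe set, which the authors made with Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes probes and summarises the probes of a set. The background setting, and whether other arrays were normalized together with these 5, is not given in the sources used here. The log base was inferred from the values: they ran from 0.830 to 12.9, which is too high for log10 and would exceed a scanner's range as natural logarithms. The labelling protocol in the labels names a whole-transcript amplification kit and a second array type, and the probe-set identifiers are those of the whole-transcript array. No detection p-values or raw intensities were used here, so no call of presence above background could be made and the number of arrays limits the precision. In its place, and chosen after the data were seen, the mean of the olfactory receptor genes on each array served as a rough floor. A named gene at or below it on every array of its dimmer group has its difference given as a bound, with the floor in place of that group's values.

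The table held 35556 probe sets. Of these, 21789 were paired with 1 gene symbol by the platform annotation, 1621 with several and 12146 with none. Entrez identifiers matched the GRCm38.p6 RefSeq gene table for 21698 probe sets, and 0 symbols needed updating. For each symbol the probe set with the highest mean over the 5 arrays was kept, which gave 19938 genes; 999 genes had more than 1 probe set. Genes that share a probe set with another gene, among them Gapdh and Cdkn1a, were therefore not tested. No filter on dim probe sets was applied.

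The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual degrees of freedom and 2.39 prior degrees of freedom per gene). Tests allowed changes in either direction, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values come from this limma fit or, for gene lists, from limma's camera with a preset inter-gene correlation of 0.01, adjusted over 34 lists, except where an estimated correlation, renormalization or a left-out array is named beside them. In all, 35 lists of pathways and cell type markers, holding 682 gene names, were written before the data were examined; the chromosomal instability list was recalled from a published signature. The list of red blood cell genes had too few measured members for a test, since at least 5 were required, and 55 of the 682 names were not measured. The genes named were fixed by rule before the data were examined: the D-type cyclins, the 15 genes that rose and the 15 that fell with the largest log2 fold change among those passing (leaving out predicted genes, small RNAs and receptor families), and in each list the 4 members with the smallest p. Other genes named are said to be chosen after their values were seen.

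A simulation used 19938 genes with each gene's residual spread and 100 changed genes of each size. The fit recovered 63% of genes changed by 2 on the log2 scale and 16% of those changed by 1, with 5 false calls. Its 5 arrays had the same range, unlike the real ones. With the controls' narrower range put in and no gene changed, limma called 279 genes higher and 43 lower, so the 5 false calls do not carry over to these arrays.

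Because the arrays differed in spread, 2 further values stand beside most results. The first is the fold change after the gene values of the 5 arrays were quantile-normalized again ("renormalized"), an alternative planned before the data were examined. The second is the percentile of a list's median fold change among 10000 random lists matched on mean expression in 50 bins ("expression-matched lists"), chosen after the spread of the arrays was seen. Such a percentile describes these arrays and is no p-value. Further alternatives were an intensity trend or robust prior in eBayes, a filter on dim genes, the mean of a gene's probe sets, median centring, array weights, the replicate number as a block, each array left out in turn, all probe sets, and for lists camera with an estimated correlation, camera on ranks and fry. Renormalization without control replicate 1 was added after the data were seen. A pseudocount, meant for values on a linear scale, was not tried, because the values are logarithms. The 5 value columns were all mapped to samples. The sequence composition of transcripts was not analysed here.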

Results

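Genome-wide expression was measured in the mammary glands of 2 rtTA control mice and 3 rtTA/cyclin D1 mice, 1 array per mouse. Cyclin D1, encoded by Ccnd1, is the regulatory subunit of the G1 kinases CDK4 and CDK6. The study's title and design ask how gene expression in the gland differs after acute induction of a cyclin D1 transgene. Of the 19938 genes tested, control replicates 1 and 2 had 305 and 712 genes above a log2 value of 5, and the cyclin D1 replicates 1, 2 and 3 had 1888, 2120 and 1597. The median gene stood at 2.81 and 2.83 in the controls and at 2.73, 2.72 and 2.82 in the cyclin D1 arrays. The SD across genes was 0.735 and 0.926 in the controls against 1.32, 1.38 and 1.20. The 3 cyclin D1 arrays correlated with one another at Pearson r of 0.955 to 0.962 across genes, whereas the 2 controls correlated at 0.779. Control 2 correlated at 0.841 to 0.884 with the cyclin D1 arrays and control 1 at 0.701 to 0.743. No pair of arrays held near-identical values.

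Fold changes followed expression level. Among the decile of genes with the highest mean expression the median log2 fold change, cyclin D1 minus control, was 1.59, and in the lowest decile it was -0.29. After renormalization these medians were 0.36 and -0.08. Gene families were also chosen after the spread was seen. The median log2 fold change was 1.42 over 59 ribosomal protein genes and 1.01 over 39 proteasome genes, which are used by every cell. It was -0.35 over 1015 olfactory receptor genes. The renormalized medians of these families were 0.12, 0.55 and -0.18. Against expression-matched lists the ribosomal genes lay at percentiles 59.9 as deposited and 72 after renormalization and the proteasome genes at 83.3 and 99.9, while the olfactory receptor genes lay at percentile 0 on both scales.

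**Figure D1:**
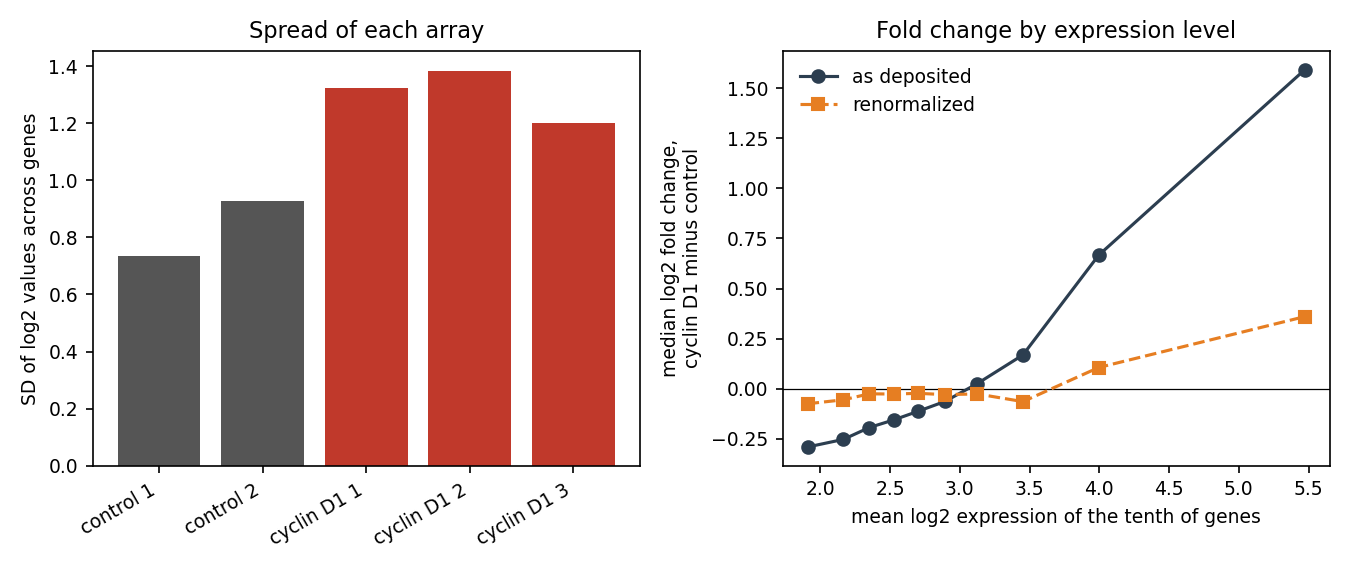
The left panel gives the SD of log2 values over 19938 genes for each array (grey, control, red, cyclin D1), and the right panel the median log2 fold change of each decile of genes against its mean log2 expression, as deposited (circles) and after renormalization (squares). The control SDs of 0.735 and 0.926 lie below those of all 3 cyclin D1 arrays, and the deposited fold change climbs from -0.29 to 1.59 with expression.

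Ccnd1 itself (probe set 10569646) did not pass the test. Its log2 expression was 3.77 ± 0.39 (SD, n = 2) in controls and 4.52 ± 0.47 (SD, n = 3) in cyclin D1 glands, a log2 difference of 0.75 (SE 0.32, limma adjusted p = 0.218), and the value of -0.14 after renormalization had the opposite sign. Control 1, at 4.04, stood above cyclin D1 replicate 3, at 4.0. Ccnd2 and Ccnd3, the other D-type cyclins, differed by 0.11 (SE 0.16, adjusted p = 0.687, with the opposite sign at -0.31 after renormalization) and 0.18 (SE 0.33, adjusted p = 0.741). The sources used here do not say whether the Ccnd1 probe set reads the transgene.

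In the genome-wide comparison 1072 genes were higher and 137 lower in cyclin D1 glands. Of the 1994 genes in the decile with the highest mean expression, 717 were higher and 1 was lower. Counts of higher genes within a list of bright genes, as given below, have to be read beside that share. As deposited, the largest rises among the genes named by rule were those of Cox6b1, a subunit of cytochrome c oxidase, by 4.68 on the log2 scale (SE 0.74, adjusted p = 0.0332) and Atp13a3, a P-type ATPase, by 4.66 (SE 0.42, adjusted p = 0.0165). Cox6b1 stood at 2.31 in control 1 and 4.75 in control 2, and after renormalization it differed by 3.72 and Atp13a3 by 4.01, neither passing. Of the 2 control values of Cox6b1, Atp13a3 and Tc2n, 1 lay at or below the mean of the olfactory receptor genes on its array, so their differences are inexact. Lcn2, a lipocalin that binds siderophores, rose by 4.56 (SE 0.69, adjusted p = 0.0312). Fth1 (ferritin heavy chain), Trf (transferrin) and Cp (ceruloplasmin, a ferroxidase) rose by 4.34, 4.31 and 3.97. B4galt1, the galactosyltransferase that forms lactose synthase with alpha-lactalbumin, rose by 4.05, and Wfdc18, a secreted proteinase inhibitor of mammary epithelium, by 3.96. Acsl4, an acyl-CoA synthetase, rose by 4.26 (SE 0.22, adjusted p = 0.0102). Nampt, which makes an NAD precursor, rose by 4.04, the nucleoside transporter gene Slc28a3 by 4.21 and the vesicle coat gene Copb1 by 3.94. Tceal9, Plet1 and Tc2n completed the 15, with 4.28, 4.12 and 4.05.

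The genes that fell changed less and were dim. C1ra, a complement protease, fell by 1.47 on the log2 scale (SE 0.18, adjusted p = 0.0207). Hamp, the iron-regulating hormone hepcidin, fell by 1.34 (SE 0.12, adjusted p = 0.0165), and Col8a2, a collagen chain, fell by 1.16. Of the other 12, Ccdc180, Tcte1, Catip, Ubqlnl, Rgs18, Plac1, Asic3, Nppa and Thap7 fell by 1.02 (Thap7) to 1.179 (Ccdc180). Zfp985, Tuba3b and Ankub1 lay at or below the mean of the olfactory receptor genes on all 3 cyclin D1 arrays and have only bounds, of -0.91, -1.0 and -1.0 or lower. Plac1 lay there on 2 of the 3 arrays and Hamp, Catip, Ubqlnl and Rgs18 on 1, so their differences are inexact. Of all 137 genes that fell, 57 lay there on all cyclin D1 arrays, and the median of -0.88 became -0.80 with bounds for them, except 4 that lay there in both groups. The 137 included 32 of the 1015 olfactory receptor genes, a family that served as the floor and that the rule for naming left out, and 0 of that family rose. Lower calls can therefore reflect a shift of dim signal between the arrays. The 15 had control means of 2.98 to 3.94 and cyclin D1 means of 1.83 to 2.76.

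Of all calls 88.7% were higher, and after renormalization 51 genes were higher and 21 lower, with 70.8% higher. All 51 of these higher genes, but 4 of the 21 lower ones, were among the deposited-scale calls; Acsl4, Tceal9, Nampt, Copb1 and Hamp passed on both scales, and the other 25 of the 30 named genes kept their sign without passing. Of the members of the 34 gene lists below, only the milk gene Plin2 and the mitotic gene Kif11 passed after renormalization. In 8975 genes, 45.0%, the 3 cyclin D1 values lay on one side of both controls, where arrays of equal range would give 20% by chance. Both controls had the narrower range, which by itself separates bright and dim genes, so the excess over 20% cannot be read as an effect of the transgene. The counts rest on few mice: they were 0 higher and 0 lower without control 1 (4973 genes at an unadjusted p under 0.05, against 5244 with all arrays), without cyclin D1 replicate 1 (3568) and without cyclin D1 replicate 2 (3491). They were 299 and 2 without cyclin D1 replicate 3, and 1365 and 1063 without control 2. Renormalized without control 1, 555 genes were higher and 894 lower.

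Milk and secretory genes of alveolar epithelium were higher as a group. Of 19 measured members 12 rose and 0 fell, or 17 rose when adjusted over the list alone, and all 19 had positive fold changes with a median log2 of 3.19. Csn3 (kappa-casein) went from 8.24 ± 0.39 (SD, n = 2) to 10.8 ± 0.07 (SD, n = 3), a 5.74-fold rise (limma adjusted p = 0.0147). Plin2, which coats lipid droplets, rose by 3.58 on the log2 scale (adjusted p = 0.0157), Xdh, needed for milk fat secretion, 9.89-fold (adjusted p = 0.0168) and Elf5, a transcription factor of alveolar differentiation, 10.8-fold (adjusted p = 0.0192). Among members chosen after their values were seen, Wap (whey acidic protein) had a log2 difference of 4.45 (SE 0.94, adjusted p = 0.0574), and Csn2 (beta-casein), already at 10.4 and 11.3 in the controls, one of 0.89 (SE 0.31, adjusted p = 0.153). The list passed camera (adjusted p = 9.03e-12) and lay at the 100th percentile of expression-matched lists on both scales. Its median was 2.60 without control 1 and 2.06 after renormalization, where Plin2 alone passed singly and Csn2 was at -0.088; with an estimated correlation the list had an adjusted p = 0.538 as deposited and 0.608 after renormalization.

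Mitotic genes also stood higher. Of 41 measured, 8 rose and 0 fell, or 13 rose when adjusted over the list alone, and 37 had positive fold changes, with a median log2 of 0.91. The members with the smallest p were Kif11, a spindle motor (2.16 ± 0.04, SD, n = 2, in controls and 4.99 ± 0.52, SD, n = 3, in cyclin D1 glands, a log2 difference of at least 2.54, limma adjusted p = 0.0179), Top2a, a topoisomerase of dividing cells (9.50-fold, adjusted p = 0.0213), Ndc80 of the kinetochore (2.43-fold, adjusted p = 0.0270) and the checkpoint gene Mad2l1 (8.45-fold, adjusted p = 0.0293). The proliferation marker Mki67, chosen after its values were seen, differed by 2.41 on the log2 scale (SE 0.54, adjusted p = 0.0664). Camera called the list (adjusted p = 3.59e-07), at the 100th percentile of expression-matched lists on both scales. The median was 0.87 without control 1 and 0.93 after renormalization, where Kif11 alone passed singly; with an estimated correlation the list had an adjusted p = 0.538 as deposited and 0.608 after renormalization.

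**Figure D2:**
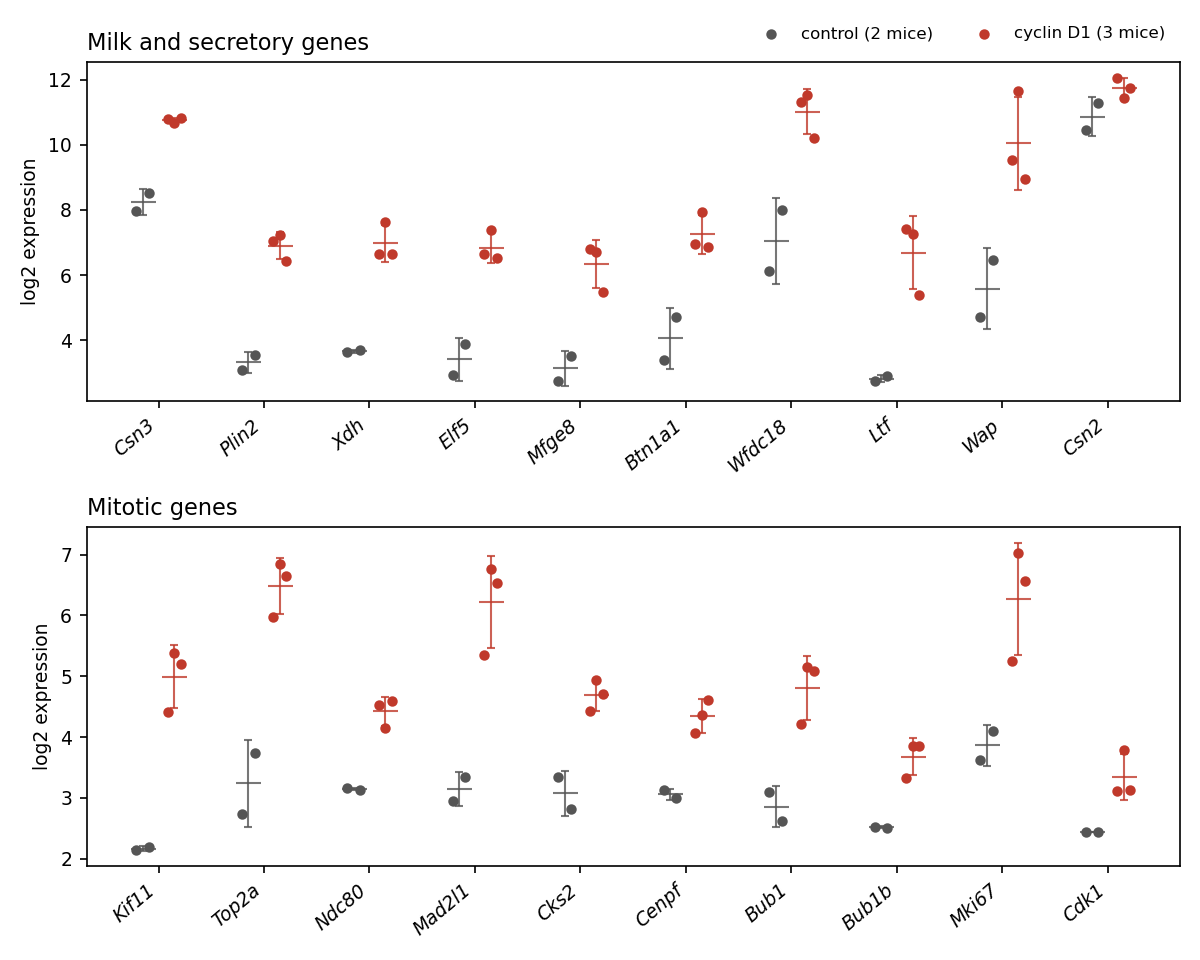
Log2 expression of 10 milk or secretory genes (top) and 10 mitotic genes (bottom) per mouse, with control in grey and cyclin D1 in red; horizontal ticks are group means and bars 1 SD (n = 2 and n = 3). Genes were chosen for display after their values were seen; the groups do not overlap for any of them, Wap, Csn2, Mki67 and Cdk1 did not pass the test over all genes, and Csn2 had the opposite sign, -0.088, after renormalization.

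Genes of a chromosomal instability signature also stood higher. Of 67 measured, 10 rose and 0 fell, or 18 rose when adjusted over the list alone, with a median log2 fold change of 0.53 (camera adjusted p = 4.56e-07, and adjusted p = 0.538 with an estimated correlation). Besides Top2a and Mad2l1, the leading members were the histone methyltransferase gene Ezh2 (5.25-fold, limma adjusted p = 0.0178) and Atad2 (2.36-fold, adjusted p = 0.0209). Renormalized, Ezh2 differed by 1.24 and Atad2 by 1.05 on the log2 scale, neither passing. This list shares 20 genes with the mitotic list and 11 with the replication list; the other 36 had a median of 0.52, with 7 that rose, at percentile 99.4 of expression-matched lists (100 after renormalization). Of 47 DNA replication genes 6 rose, or 11 when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 4.66e-04, and adjusted p = 0.538 with an estimated correlation). Gins4 of the replicative helicase rose from 2.74 and 1.74 in the controls to 5.62 ± 0.55 (SD, n = 3), the primase subunit gene Prim1 5.47-fold, the polymerase gene Pola1 3.22-fold and Orc6 of the origin recognition complex 2.67-fold. Gins4 in control 2, and Kif11 in both controls, lay below the mean of the olfactory receptor genes (2.52 in control 1 and 2.38 in control 2), so no exact difference is given for them. Of 28 DNA repair genes 2 rose, or 8 when adjusted over the list alone, with a median of 0.51 (camera adjusted p = 9.34e-04, and adjusted p = 0.538 with an estimated correlation): the checkpoint kinase gene Atr (2.28-fold) and Clspn (1.95-fold), while Msh6 (log2 1.11, adjusted p = 0.0511) and Chek1 (1.88, adjusted p = 0.0755) did not pass over all genes. All 3 lists kept camera's call after renormalization, with medians of 0.52, 0.28 and 0.47, but each then had an adjusted p = 0.608 with an estimated correlation. Without cyclin D1 replicate 2 the chromosomal instability median was 0.33, and without control 2 the replication list was not called (adjusted p = 0.0571).

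Among the D-type cyclins, their kinases and inhibitors, the RB family and the E2F factors, 1 of 24 rose and 1 fell, or 3 and 1 when adjusted over the list alone. The pocket protein gene Rb1 rose by 2.69 on the log2 scale (SE 0.35, limma adjusted p = 0.0238), and Cdkn2d, which encodes a CDK4 and CDK6 inhibitor, fell by 0.86 (SE 0.13, adjusted p = 0.0321). Renormalized, Rb1 differed by 1.05 and Cdkn2d by -0.93, neither passing. E2f5 differed by 0.79 and Tfdp2 by 0.77, the latter with a value of -0.50 after renormalization. Both passed when adjusted over the list alone but not over all genes. E2f5 lay at or below the mean of the olfactory receptor genes in 1 control, so its difference is inexact. The list's median was 0.26 (camera adjusted p = 0.0302, and adjusted p = 0.538 with an estimated correlation), at percentile 93.5 of expression-matched lists, and 0.12 after renormalization (camera adjusted p = 0.456). It was not called without control 1 (adjusted p = 0.0653), control 2 (0.123, median 0.42) or cyclin D1 replicate 2 (0.0556).

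Oxidative phosphorylation genes had a median log2 fold change of 1.57. Of 33 measured, 11 rose and 0 fell, or 23 when adjusted over the list alone, among them Atp5a1 of ATP synthase (4.78-fold), Uqcrc2 of complex III (5.20-fold), Ndufs1 of complex I (3.81-fold) and Cox7b (6.02-fold). On the renormalized scale these genes differed by only 0.87, 0.96, 0.74 and 0.79 in log2 units, and 0 of the 33 passed singly. Camera's adjusted p was 3.55e-12 (adjusted p = 0.538 with an estimated correlation), but the list lay at percentile 94.2 of expression-matched lists; after renormalization its median was 0.60, at percentile 99.8 (camera adjusted p = 5.99e-03, and adjusted p = 0.645 with an estimated correlation). Renormalized without control 1 it was 0.36 and not called (adjusted p = 0.0666). Of 16 genes of the unfolded protein response 3 rose, or 10 when adjusted over the list alone: Sel1l by 0.96 on the log2 scale, the chaperone gene Hspa5 by 2.93 and Dnajb9 by 2.94, while the difference of 2.75 for the asparagine synthetase gene Asns did not pass over all genes. The median of the list was 0.86 (camera adjusted p = 1.12e-04, and adjusted p = 0.538 with an estimated correlation), at percentile 84.9 of expression-matched lists, and 0.41 after renormalization (camera adjusted p = 0.0571). Of 12 microRNA processing genes 4 rose, both over all genes and adjusted over the list alone: the helicase genes Ddx5 by 3.01 and Ddx17 by 1.62, Dicer1, which cuts microRNA precursors, by 2.26 and the Argonaute gene Ago3 by 0.77. The microRNA processing median was 0.39 (camera adjusted p = 0.0302, and adjusted p = 0.538 with an estimated correlation), at percentile 89.9, and 0.35 after renormalization (camera adjusted p = 0.129). It was not called without control 2 (adjusted p = 0.0918) or cyclin D1 replicate 2 (0.0524), and the median was 0.17 with bounds for the 3 members at or below the olfactory receptor mean in both controls. Of 13 glycolytic genes Ldha (lactate dehydrogenase) rose by 1.59, and 4 passed when adjusted over the list alone, whereas Pgk1 at 1.67, Hk1 at 3.72 and Pfkl at 0.51 did not pass over all genes. The glycolytic median was 0.50 (camera adjusted p = 8.95e-03, and adjusted p = 0.538 with an estimated correlation), at percentile 39.3 of expression-matched lists, and 0.14 after renormalization (camera adjusted p = 0.634). It was 0.24 and not called without control 1 (adjusted p = 0.0653), -0.089 when renormalized without control 1, and 0.31 without cyclin D1 replicate 1.

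Of 18 genes of fatty acid and triglyceride synthesis 1 rose, also when adjusted over the list alone: Acaca, which makes malonyl-CoA, by 3.19 on the log2 scale (SE 0.59, limma adjusted p = 0.0447). Lpin1 at 0.80, Me1 at 1.90 and Scd1 at 0.68, with the opposite sign at -0.72 after renormalization, did not pass. The list's median of 0.51 (camera adjusted p = 0.0148, and adjusted p = 0.630 with an estimated correlation) became -0.30 after renormalization, at percentiles 10.7 and 7.66 of expression-matched lists. It was 0.35 without control 1 (adjusted p = 0.116), 0.32 without cyclin D1 replicate 1 (adjusted p = 0.109) and 0.80 without cyclin D1 replicate 3. Among adipocyte markers 2 of 17 rose, or 3 when adjusted over the list alone: the fatty acid transporter gene Cd36 by 2.36 and the growth hormone receptor gene Ghr by 1.36, the latter at -0.42 after renormalization. Lpl (1.85) and Cebpa (0.86) did not pass over all genes. The adipocyte list as a whole was not called (median 0.33, camera adjusted p = 0.0976), its median turned to -0.45 after renormalization, and it lay at percentiles 2.46 and 1.63 of expression-matched lists on the deposited and renormalized scales. The deposited median was 0.62 without cyclin D1 replicate 2 and -0.053 without cyclin D1 replicate 1.

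Of 20 luminal epithelial markers 3 rose, also when adjusted over the list alone: the transcription factor gene Ehf 6.30-fold, the adhesion gene Epcam 5.63-fold and E-cadherin, Cdh1, 2.59-fold, all with limma adjusted p of 0.0168 to 0.0228. Esrp1 at 1.5 on the log2 scale did not pass, nor did the luminal keratin genes Krt8 at 1.44 and Krt18 at 0.92, chosen after their values were seen; Krt18 was at -0.55 after renormalization. The list's median was 0.59 (camera adjusted p = 1.19e-03, and 0.538 with an estimated correlation), at percentile 86.5 of expression-matched lists, and 0.21 after renormalization (camera adjusted p = 0.129). Among 15 basal and myoepithelial markers Itga6 rose by 2.21 and Acta2, smooth muscle actin, by 2.48, and the same 2 passed when adjusted over the list alone. Renormalized, Itga6 was at 0.50 and Acta2 at 0.92, neither passing. The differences of -0.78 for Dsc3 and 1.66 for Myh11 did not pass. That list's median was -0.08 and its mean 0.40 (camera adjusted p = 0.464, upward), with a median of 0.03 after renormalization, 0.045 without control 1 and 0.029 without cyclin D1 replicate 2. Of 11 keratinocyte markers the cornified envelope gene Lce1a1 fell, with a bound of -0.66 or lower (adjusted p = 0.0235), also over the list alone, while Tgm3 at -0.30, Lor and Krt1 did not pass, the last 2 lying at or below the olfactory receptor mean in both controls; this list was the only one camera called lower (median -0.27, adjusted p = 0.0214, and 0.538 with an estimated correlation), at percentile 15 of expression-matched lists and not called after renormalization (median -0.18, adjusted p = 0.129). Nor was it called without control 1 (median -0.15, adjusted p = 0.160), and without control 2 its median was -0.41.

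The other 19 lists were not called, and their camera adjusted p ranged from 0.0620 for skeletal muscle to 0.948 for immediate-early genes and for Schwann cells and nerve. A few of their members passed over all genes: Fabp3 of the brown adipocyte list rose by 3.89, Hlf and Nr1d2 of the circadian list by 1.27 and 1.28, the sterol gene Nsdhl by 1.1 and the immediate-early gene Zfp36 by 0.97, while the T cell adaptor gene Lat fell by 0.77. Nr1d2 was at -0.13 after renormalization. When adjusted over the list alone, 3 circadian genes and 3 p53 targets passed. Median log2 fold changes were 0.27 for p53 targets, 0.55 for cholesterol synthesis, 0.53 for interferon-stimulated genes, 0.16 for circadian genes, 0.45 for brown adipocyte markers, -0.10 for hormone receptors and response genes, -0.20 for Wnt targets, -0.12 for Notch targets, 0.10 for MHC class II and -0.04 for immediate-early genes. For cells that the gland or its dissection could add, the medians were -0.02 for T cells, -0.20 for B cells, -0.03 for plasma cells, 0.05 for macrophages, -0.19 for granulocytes and mast cells, 0.10 for fibroblasts and matrix, 0.05 for endothelium, -0.17 for skeletal muscle and -0.03 for Schwann cells and nerve. After renormalization the cholesterol synthesis and p53 target medians were 0.05 and 0.10, and without control 1 they were 0.25 and 0.14. Many of these medians were near 0 and moved with single arrays. Without control 1 they were 0.054 for circadian genes, -0.014 for fibroblasts and -0.025 for MHC class II. Without control 2 they turned to 0.095 for hormone response genes, 0.094 for Notch targets, 0.085 for immediate-early genes, 0.097 for T cells, 0.046 for Schwann cells and nerve and 0.021 for plasma cells, and were -0.08 for Wnt targets and -0.068 for granulocytes and mast cells. Without cyclin D1 replicate 1 they were 0.20 for brown adipocytes, 0.21 for T cells and -0.13 for macrophages. Without cyclin D1 replicate 2 they were 0.14 for interferon-stimulated genes, 0.78 for brown adipocytes, 0.25 for macrophages, 0.22 for fibroblasts, -0.39 for B cells, 0.12 for endothelium and -0.12 for skeletal muscle, and turned to 0.011 for hormone response genes, 0.038 for immediate-early genes, 0.032 for plasma cells and 0.025 for Schwann cells and nerve. Without cyclin D1 replicate 3 brown adipocytes were at 0.72 and T cells at 0.081. The mean of the T cell markers was 3.57 in cyclin D1 replicate 2 against 2.65 in replicates 1 and 3 and 2.95 and 3.1 in the controls, and their median was -0.34 without replicate 2. The macrophage, fibroblast and MHC class II medians turned after renormalization, to -0.05, -0.17 and -0.06. With each array centred on its median, those of T cells, plasma cells, Schwann cells and nerve, and immediate-early genes turned to 0.052, 0.043, 0.044 and 0.032. Median, mean and test differed in sign for hormone response genes (mean 0.18, camera upward), immediate-early genes (mean 6.19e-04, camera downward) and Schwann cells and nerve (mean -0.0068, camera upward).

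**Figure D3:**
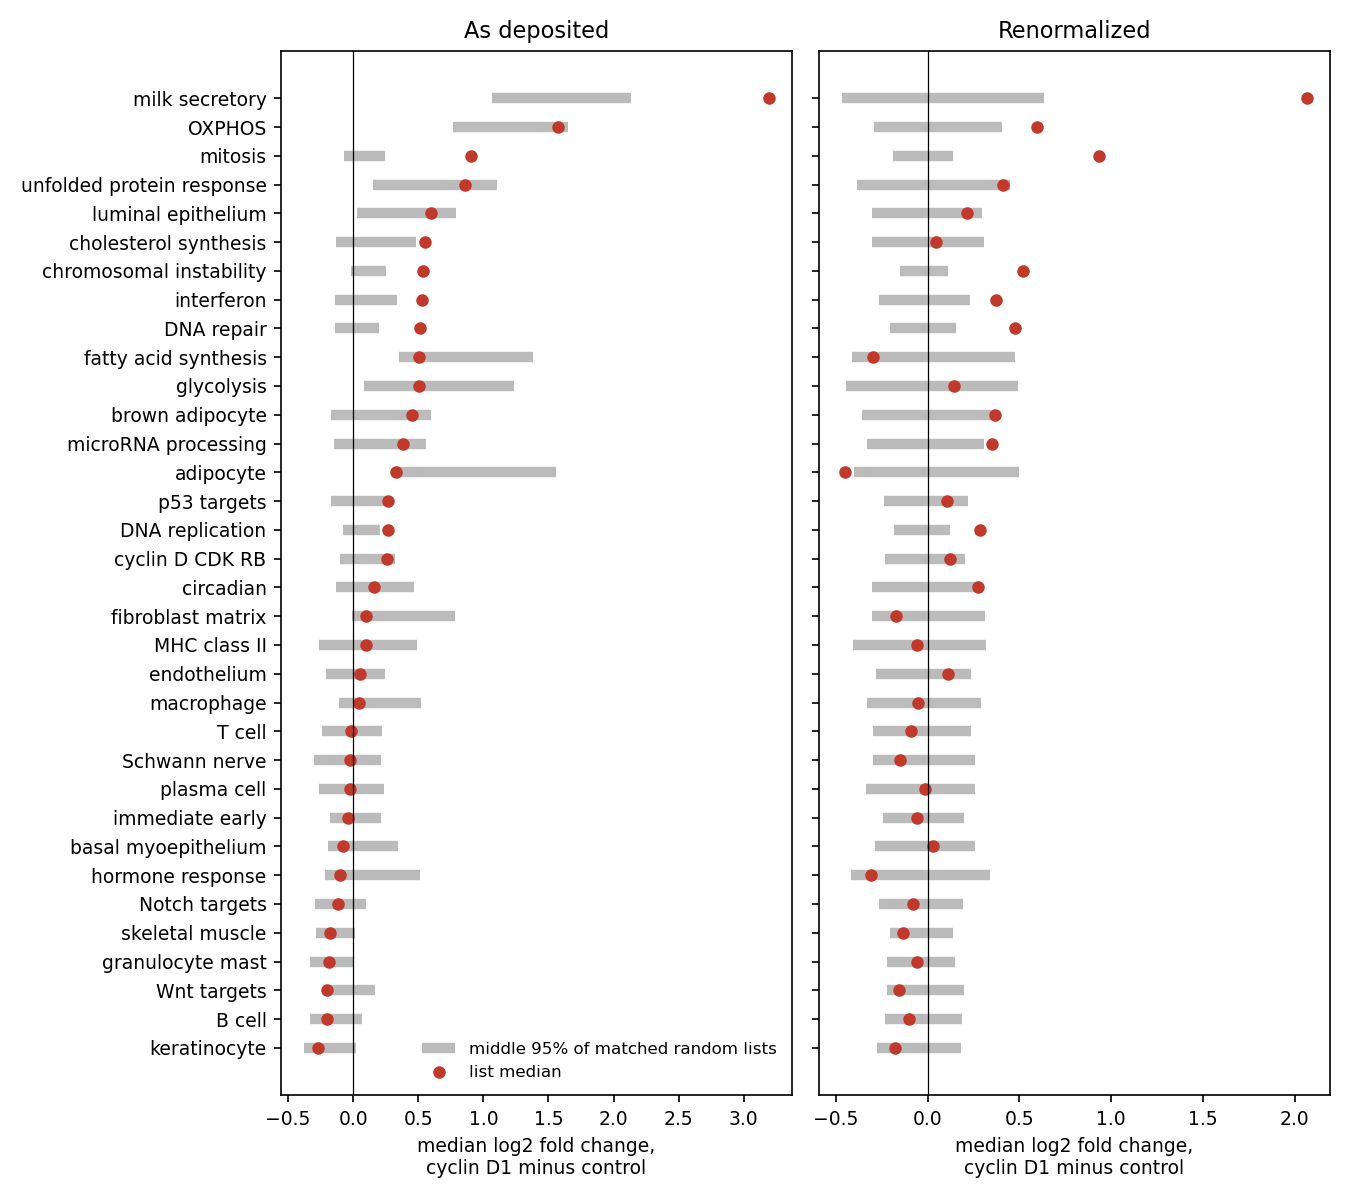
Median log2 fold change (cyclin D1 minus control) of 34 gene lists as red points, as deposited on the left and after renormalization on the right; grey bars span the middle 95% of the medians of 10000 expression-matched random lists. The milk, mitosis, chromosomal instability, DNA repair, DNA replication and interferon lists lie to the right of the grey bars in both panels. The interferon list was not called and rests on cyclin D1 replicate 2. The adipocyte list lies at or below the lower end of its bar.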

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

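Probe sets outside the gene comparison also differed between the groups. Of the 13767 probe sets without 1 gene symbol, 332 were higher and 125 lower in the cyclin D1 arrays when all 35556 probe sets were fitted with limma (adjusted p threshold 0.05). The 332 drew attention because their signal lay above the controls in data that no gene comparison used, while the 125 lay below. Over all 35556 probe sets that fit called 1032 higher and 154 lower. The 332 were thus no larger a share of their probe sets than the 1032 were of all, whereas most of the 154 lower calls fell among these probe sets. Neither set is named here.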

How the results depend on the processing

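Of the settings here, the renormalized fit without control 1 was chosen after the data were seen. The 1072 higher genes became 622 with an intensity trend, 263 with array weights, 51 after renormalization and 555 renormalized without control 1. The 137 lower genes became 56 with only genes above the median mean, 21 after renormalization, 4 with array weights and 894 renormalized without control 1. Leaving out 1 array gave 0 to 1365 higher and 0 to 1063 lower genes; with a control left out, the lone control is assumed to vary like the cyclin D1 arrays. The cause was not tested, except that a filter and a left-out array each leave fewer genes or mice. The 12 lists called higher became 4 among the brighter genes, 6 after renormalization, 5 renormalized without control 1, and 0 with an estimated correlation or with fry; the 1 called lower became 0 in the first 2 of these and with an estimated correlation or fry, and in the other the keratinocyte call was lost too and the 1 list called lower was that of fibroblasts and matrix (adjusted p = 0.0202). Left-out arrays gave 9 to 14 lists higher and 0 to 3 lower. The log2 difference of Ccnd1 was 0.48 to 1.03 over left-out arrays and -0.14 after renormalization, and passed under no setting. Replicate numbers 1 and 2 occur in both groups without a stated pairing. Same-numbered arrays' deviations from the group means correlated at -0.03 and 0.13, and crossed pairs at -0.13 and 0.03. The deviations of the 2 controls are exact opposites, so these values are not separate checks of a pairing. With the replicate number as a block (1 residual degree of freedom), 1137 genes were higher, 10 lower, 15 lists higher and 2 lower. Renormalized values with the opposite sign were, among others, -0.31 for Ccnd2, -0.13 for Nr1d2, -0.45 for the adipocyte list, -0.50 for Tfdp2, -0.72 for Scd1, -0.088 for Csn2, -0.42 for Ghr, -0.55 for Krt18 and -0.30 for the fatty acid synthesis list; renormalized without control 1 they were -0.38 for Scd1, -0.14 for Pgk1, -0.11 for Csn2, -0.14 for Krt18 and -0.36 for that list. Of 1262 values for the 91 genes followed, 770 kept direction and side of the threshold, 467 lost the call, 16 gained it and 9 reversed. A pseudocount of the kind used for linear values was not run on these logarithms, and signal over background could not be assessed.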

Other observations

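Some lists that camera did not call stood apart from expression-matched lists. The tests chosen only after the result was seen were the share of higher calls lost on renormalization, the simulation of compressed controls, the split of unadjusted calls and the comparisons with luminal markers. Interferon-stimulated genes had a median log2 fold change of 0.53 over 19 genes, at percentile 99.9 as deposited and 99.8 after renormalization, but this rested on cyclin D1 replicate 2. Their mean log2 value was 2.93 and 3.08 in the controls and 3.23, 4.37 and 3.07 in cyclin D1 replicates 1, 2 and 3, and without replicate 2 the median was 0.14. The mean of the T cell markers stood apart in the same array, with Il7r at 5.58 against 3.09 and 2.87 in replicates 1 and 3 and 3.31 and 4.42 in the controls, as did Ms4a1 of B cells at 4.44 against 2.41, 2.17, 2.73 and 3.37, both chosen after their values were seen. Other members did not: Cd4 was at 2.96 there against 2.99 in control 1, and Cd8a at 3.32 against 3.38 in control 2. Nor did the B cell mean stand far apart, at 2.84 there against 2.68 and 2.79 in the controls. None of the 19 interferon-stimulated genes passed limma's test singly. Adipocyte markers lay at the low end, at percentile 2.46 as deposited and 1.63 after renormalization. Their median of 0.33 became 0.62 without cyclin D1 replicate 2 and -0.05 without cyclin D1 replicate 1. Adipoq, chosen after its values were seen, stood at 7.57 and 8.38 in the controls and at 8.66, 6.43 and 8.53 in the cyclin D1 glands.

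Far more genes were higher (1072) than lower (137) in cyclin D1 glands; once the 5 arrays were given the same distribution, 95.2% of the higher calls ended as their median log2 fold change went from 1.86 (median SE 0.25) to 1.00 (0.24), 989 keeping their sign and 777 an unadjusted p under 0.05. Of the lower calls 97.1% ended, but their median went only from -0.88 (SE 0.15) to -0.85 (0.16) and all 137 kept their sign and an unadjusted p under 0.05, so that these calls ended in the adjustment over all genes. In a simulation with no gene changed, and control arrays compressed by the observed slopes of 0.419 and 0.630, limma called 279 genes higher and 43 lower, and 0 in either direction after renormalization. Those slopes were fitted to these same arrays, each control against the mean of the cyclin D1 arrays. A true group difference would be built into them, so the simulation cannot separate it from a narrower range. Without control 1 the brightest decile of genes kept a median of 1.20 against 1.59. By the bound set before this value was seen, that would exclude control 1 alone. The bound was set aside after the values were seen, since it follows the trend with expression and not the count of calls. The count without control 1 cannot decide either, as it rests on a lone control. It was likewise 0 higher and 0 lower without cyclin D1 replicate 1 and without cyclin D1 replicate 2. With all arrays, 61.7% of the genes at an unadjusted p under 0.05 were higher as deposited and 49.8% after renormalization. Without control 1 the split leaned to lower genes on both scales, but that fit rests on a lone control too and cannot decide. The narrower range of both controls and control 1 alone therefore cannot be told apart as sources of the excess, nor from a property of the glands, because both narrow arrays are the controls. RNA quality and labelling of the arrays were not assessed here.

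The mitotic median lay at the 100th percentile of expression-matched lists, deposited and renormalized, and so passed the bound set against signal range alone. That bound cannot exclude the signal range. Proteasome genes reached percentile 99.9 after renormalization, and olfactory receptor genes percentile 0 on both scales. The random lists also hold unrelated genes, whereas the estimated correlation within the mitotic list was 0.44. Giving the arrays the same distribution left a mitotic median of 0.93, so that step did not remove the difference. More luminal epithelium stays open: the mitotic median exceeded that of luminal markers by 0.72 after renormalization (permutation p over genes = 0.00455) and by 0.50 when control 1 was also left out (p = 0.045), but by 0.31 as deposited (p = 0.341) and by 0.18 as deposited without control 1 (p = 0.71). Genes are not independent replicates in these tests. The transgene, the reproductive stage of the mice and sequence composition were not tested as explanations.

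The milk genes also lay at the 100th percentile of expression-matched lists on both scales. For the reasons given for the mitotic genes, this does not exclude the signal range. Random lists were matched on the mean over both groups, so a list brighter in the cyclin D1 glands was set beside genes dimmer there. Giving the arrays the same distribution left a milk median of 2.06, so that step did not remove the difference. The median of the milk genes exceeded the luminal one by 1.85 after renormalization (permutation p over genes = 7.00e-05). On the other scales, with and without control 1, it did so by 1.81 to 2.59. More luminal epithelium is not excluded by these gaps, because the lists were not matched in brightness and fold changes climbed with expression. Array means were 5.26 to 9.16 for the milk genes and 3.35 to 4.26 for the luminal markers. Genes are not independent replicates in this test either. The transgene, the reproductive stage of the mice, which the sources used here do not give, and a shift among luminal cell types were not tested.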
